A study of Homo sapiens with 4 samples.

How the data were processed

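Gene expression was measured in 4 libraries, 1 for each of H929 and KMS28BM before and after sorting on a microfluidic chip. Per the labels' protocols, total RNA was extracted with Trizol, polyadenylated RNA was selected on oligo-dT beads and fragmented, and paired-end libraries were sequenced on an Illumina NovaSeq. Groups were taken from the sample labels; the series title appears to name the libraries with the A suffix, labelled after sorting, as the unsorted ones, and this could not be settled from the values.

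The deposited values are FPKM (fragments scaled by transcript length and library size), per the file headers, in 1 table per line with 60612 human Ensembl genes each. Per the submitters' processing notes, Bowtie 0.12.2, HISAT2 2.0 and StringTie 1.3.0 were used, with no role or order given. The same notes name the build mm8, which is a mouse build and does not match the human gene IDs; the human build and annotation are not given in the sources used here, so no coordinates are printed. Between 36942 and 39183 genes per library are listed at a floor of 0.0001 FPKM, and between 22 and 27 per library below it. Deposited fold ratios are the FPKM labelled after sorting over that labelled before, floor included, and the deposited log2 values are their logarithms. The deposited p-values and q-values are the authors' own; the test behind them is not given in the sources used here. Whether the 2 tables were normalized together is not given either, so tests were made only on ratios within a line.

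StringTie-type estimates split reads between overlapping transcripts, so a read-through gene, a pseudogene or a small RNA inside a host gene can trade signal with its neighbour. For genes considered for naming, the share of 50-base words of their transcripts that also occur in another gene was counted in the GENCODE release 29 transcripts. GC content, length and gene type came from the same release by gene ID; 58394 IDs matched, and 99.4% of the 12294 genes at 1 FPKM or more in any library had a GC content and length. Depth was estimated from the pile-up of FPKM times length, within 1%, at the worth of 1 fragment in genes with a single annotated transcript, which held between 315 and 343 such genes per library. It came to between 21.2 and 24.8 M (mega) fragments, and 1 FPKM on a transcript of 2000 bases then stands for between 42.4 and 49.5 fragments. No 2 libraries held identical values.

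For each line, the log2 ratio of FPKM plus 1, labelled after over labelled before sorting, was taken for genes at 1 FPKM or more in either library, and genes at 2-fold or more were counted; no p-value is attached. A change shared by the lines was tested with limma 3.58.1 in R 4.3.3 on log2 of FPKM plus 1, with line and sorting as terms, moderated spread with a trend, and Benjamini-Hochberg adjustment over all genes tested. Gene lists, 38 in all, were fixed before the data were examined. Each list's median was placed among 10000 random lists of the same size drawn within 10 bins of mean expression, as a description of the libraries; lists with under 3 measured members got no median. In the shared fit, lists were tested with camera at a preset correlation of 0.01 and with an estimated one, and with fry. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

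Genes were named by a rule fixed before the data were examined: per line the 10 highest and 10 lowest ratios; the 10 highest and 10 lowest by the smaller ratio of the lines where the signs matched; the 5 largest each way where signs differed; per list up to 2 members at each end by the mean ratio; the myeloma class list; and the 5 highest and 5 lowest between lines. Other members of the lists are named as examples chosen after their values were seen, as was a second ranking, of protein-coding genes at 5 FPKM or more with under 20% of words shared, by the smaller in size of the ratio as deposited and with the trend below removed, where both had the same sign; its first 15 genes each way were considered. Some genes that the rule names are not reported here.

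Alternatives were a pseudocount of 0.1 or 5, no filter or 5 FPKM, centring on the median of well measured genes, a trimmed-mean scaling (30% of ratios and 5% of levels trimmed at each end), rescaling to genes with known symbols outside mitochondrial and immunoglobulin genes, thresholds of 1.5-fold and 4-fold, and no trend in the moderation. The trimmed mean gave each gene above the floor in both libraries the same weight, so genes under 1 FPKM entered it. Among genes at 5 FPKM or more the median ratio as deposited was already 0.03 in H929 and 0.0034 in KMS28BM. This scaling moved those genes away from 0, up in H929 and down in KMS28BM. Added after the data were seen was removal of a cubic trend in GC content and log2 length. It was fitted per line on protein-coding genes and removed from all genes with both values. Also added then were a restriction to protein-coding genes, random lists matched on GC content as well, and reversing the KMS28BM ratios. So was a restriction of 2 list medians to members measured in both lines. On data simulated from the real before-sorting values with a GC trend and noise of 0.25, all of the 4-fold genes were recovered with the trend removed in H929 (11035 genes) and in KMS28BM (9675 genes). For 2-fold genes, which sit on the threshold, 38% and 35% were recovered, and 0 and 1 unchanged genes passed. The simulated noise was below the spread of the real ratios as deposited, trend included. In the expression bin of DNAJB1, for example, that spread was 0.42 in H929 and 0.41 in KMS28BM. The simulation also held no reads split between genes. The small number of unchanged genes that passed therefore does not carry over to the real counts. The shared test recovered all changed genes over 8652 genes and called 8 of 8452 unchanged ones. It was simulated with the trend removed, while the shared calls reported keep the trend. In the real data ZDHHC18, with ratios of 1.54 in H929 and 1.31 in KMS28BM, was not called (SE 0.40, adjusted p = 0.119, limma). The simulated recovery of 2-fold genes therefore does not hold for the shared calls reported.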

Results

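RNA was measured in 4 libraries of human multiple myeloma cells, a cancer of plasma cells. H929 and KMS28BM are established myeloma lines, and each gave 1 library labelled before sorting and 1 labelled after sorting on a microfluidic chip. The series title appears to read the other way, naming as unsorted the cells that the sample labels place after sorting. The sample labels are followed here, and each direction below is that of the library labelled after sorting against the library labelled before sorting; all of them would turn round if the title were right. At least 1 FPKM was listed for 10782 genes in the H929 library labelled before sorting and 9740 in the one labelled after, and for 9303 and 10177 genes in the KMS28BM libraries. Depth, estimated from the smallest steps of the values, was 24.8 and 22.8 M fragments in H929 and 21.2 and 23.4 M in KMS28BM. There was 1 library per group, so no difference within a line has a replicate check. Ratios are log2 of the FPKM plus 1, which understates the change of low genes.

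The first comparison asked how H929 cells labelled after sorting differed from those labelled before. Heat shock genes were higher, and genes of the integrated stress response, the interferon response and plasma cell identity were lower. Of 19 heat shock genes measured, 6 were 2-fold or more higher and 0 were 2-fold lower, with a median log2 ratio of 0.67. HSPA6 (ENSG00000173110), a strictly inducible HSP70 gene, was listed at 24.3 FPKM, a log2 ratio of 3.66. HSPA1A and HSPA1B, the main inducible HSP70 genes, stood at 196 against 30.5 FPKM and 351 against 53.5 FPKM. DNAJB1 (ENSG00000132002), an HSP40 co-chaperone, stood at 141 against 30.6 FPKM, a log2 ratio of 2.17. The constitutive chaperone HSPA8 was at 337 against 153 FPKM. HSPA1A shared 72.6% of its 50-base words with HSPA1B, and HSPA6 shared 45.5% with HSPA7, so their reads can be split between copies; DNAJB1 shared 2.57% with other genes.

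**Figure D1:**
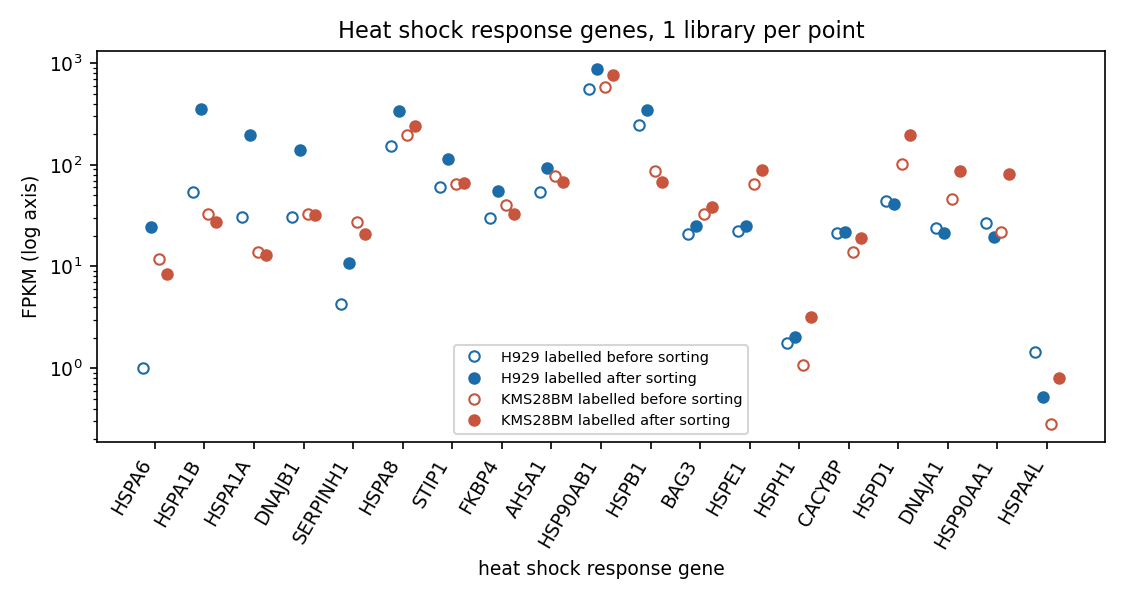
FPKM on a log axis of the 19 heat shock response genes measured in H929, with 1 point per library; open points are labelled before sorting and filled points after, blue for H929 and red for KMS28BM. HSPA6, HSPA1B, HSPA1A and DNAJB1 stand apart in H929, with log2 ratios of 3.66, 2.69, 2.65 and 2.17, and their KMS28BM points lie close together.

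Of 27 genes of the integrated stress and amino acid response, which ATF4 controls, 9 were 2-fold or more lower in the H929 library labelled after sorting and 1 was higher, with a median log2 ratio of -0.67. SESN2 was at 19.6 against 56.0 FPKM, TRIB3 at 13.1 against 33.2, CHAC1 at 3.35 against 8.58, and CTH, an enzyme of cysteine synthesis, at 9.77 against 25.7. DDIT4, an inhibitor of mTORC1, was the exception, at 142 against 23.8 FPKM, a log2 ratio of 2.52. All 16 interferon-stimulated genes measured had ratios below 0 and 4 were 2-fold or more lower, with a median of -0.77; IFIT3 was at 1.10 against 6.17 FPKM. Of 23 plasma cell and myeloma genes, 4 were 2-fold or more lower, with a median of -0.59. IRF4 (ENSG00000137265), a transcription factor on which myeloma cells depend, stood at 55.1 against 260 FPKM, a log2 ratio of -2.22. BMI1, a Polycomb gene, was at 22.1 against 112 FPKM, ELL2 at 10.3 against 31.3, CD38 at 6.89 against 16.1, and XBP1 at 191 against 305. BMI1 shared 28.2% of its words with the read-through COMMD3-BMI1. Immunoglobulin transcripts, the main product of plasma cells, went the other way, at 6.84% of the summed FPKM against 5.35%.

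Cell cycle genes stood slightly higher in the same H929 library. The 28 G1/S genes had a median of 0.38, with RRM2, a ribonucleotide reductase subunit, at 101 against 42.3 FPKM, and the 30 G2/M genes a median of 0.28, with PLK1, AURKB and CDC20 more than 2-fold higher, KIF11 and HJURP more than 2-fold lower and 16 ratios above 0. The G2/M median was -0.051 without a filter on low values. The nuclear genes of oxidative phosphorylation had a median of 0.31 and the proteasome genes of 0.29, within the middle 95% of random lists matched on expression but at percentiles 99.95 and 99.98 of lists matched on GC content too. Genes of adhesion and homing had a median of -0.32, with the integrin ITGA4 at 8.53 against 31.7 FPKM and the chemokine receptor CCR1 at 34.3 against 80.4. Genes of the oxidative stress response had a median of -0.20, with HMOX1 at 40.3 against 136.71 FPKM; this median was 0.046 with a trimmed-mean scaling. The heat shock median lay above all 10000 random lists of the same size and expression, and the stress and plasma cell medians below all of them. The interferon median lay at percentile 0.01, G1/S at 99.99, G2/M at 99.89, oxidative stress at 1.18 (2.81 with GC content matched too), adhesion at 1.61 (3.34), oxidative phosphorylation at 96.79 and the proteasome at 97.49. Mitochondrially encoded transcripts made up 20.1% of the summed FPKM against 26.0%, and all 15 of them had ratios below 0, with a median of -0.31 that lay below all random lists matched on expression and at percentile 7.9 of those matched on GC content too.

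Over the 11083 H929 genes with 1 FPKM or more in either library, 176 were 2-fold or more higher and 573 were lower in the library labelled after sorting. With a trimmed-mean scaling, which moved the median ratio of all genes from -0.11 to 0.11, the split was 378 higher and 328 lower, and the medians were 0.92 for heat shock, -0.48 for the integrated stress response, -0.58 for the interferon genes and -0.38 for the plasma cell genes. The largest ratios belonged mostly to gene models that share sequence with a neighbour or copy. Among the 10 highest, 9 were not protein-coding or shared more than 20% of their words with another gene, as did all of the 10 lowest. Z83844, RPS26P19, FAM47E-STBD1, RPL13AP7, AL662899, FMC1-LUC7L2 and AC068587 were among the highest, and SNORD58B, RNVU1-14, AL662884, CBSL, AL358472, CORO7-PAM16, MIR4707, AC006001, BOLA2 and RNVU1-6 were the lowest; they are uncertain. Protein-coding genes with little shared sequence, a ranking chosen after the data were seen, were led by HILPDA, a lipid droplet protein, at 33.6 against 3.53 FPKM. They included MRPS2 at 40.3 against 5.63, the cell cycle inhibitor CDKN2D at 19.5 against 3.15 and RUNX3 at 16.3 against 3.27. The lower end held AMPD1, an AMP deaminase, at 14.5 against 77.5 FPKM, KCTD20 at 5.47 against 33.8 and PGRMC2 at 4.53 against 25.1.

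Ratios in H929 followed the GC content of the transcripts. Across 9262 protein-coding genes, Spearman's rho between ratio and GC content was 0.54, and genes are not independent replicates. The GC decile with a median of 37.7% had a median ratio of -0.64, and that with 64.5% had 0.22. Genes 2-fold lower had a median GC content of 41.2% and a median transcript length of 4567 bases, against 50.1% and 3151 bases over these genes. A fitted trend in GC content and length, an alternative added after the data were seen, took up 30.5% of the variance. With it removed, 262 genes were higher and 259 lower, and 125 of the 176 higher and 203 of the 573 lower genes kept their place. The medians were then 0.69 for heat shock, -0.60 for the integrated stress response, -0.80 for the interferon genes, -0.42 for the plasma cell genes, 0.50 for G1/S and 0.38 for G2/M, while adhesion came to -0.08, oxidative stress to -0.02 and oxidative phosphorylation and the proteasome each to 0.34. Of the G2/M genes 0 were then 2-fold higher and 1 was lower. Of the plasma cell genes 2, of the integrated stress genes 6 and of the interferon genes 5 were then 2-fold lower, and 6 heat shock genes were 2-fold higher. IRF4 was at -1.93, SESN2 at -1.59, CD38 at -0.64 and DNAJB1 at 2.07.

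**Figure D2:**
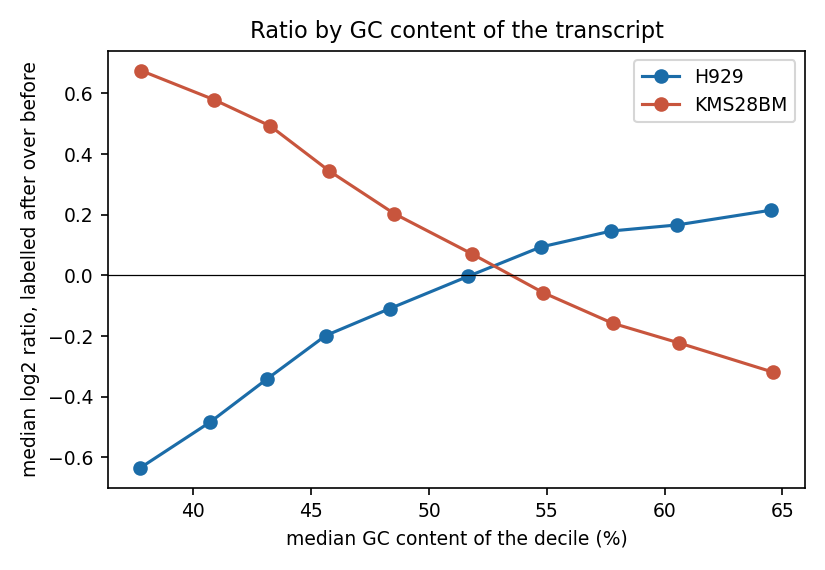
Median log2 ratio, labelled after over before sorting, of protein-coding genes in 10 bins of transcript GC content (percent), with 1 line per cell line. H929 goes from -0.64 in the lowest bin to 0.22 in the highest, and KMS28BM from 0.68 to -0.32.

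The same question was put to KMS28BM. Here some genes of mitosis and some p53 targets were higher in the library labelled after sorting, and the heat shock and stress genes that stood out in H929 differed little. Of 31 G2/M genes, 7 were 2-fold or more higher and 0 lower, with a median of 0.45; NUSAP1, a spindle protein, was at 27.4 against 9.37 FPKM, DLGAP5 at 5.54 against 1.08 and TOP2A at 5.63, a log2 ratio of 1.46. Of 22 p53 targets, 5 were 2-fold or more higher, with a median of 0.35, led by PMAIP1 (ENSG00000141682), which encodes the BH3-only protein NOXA, at 56.5 against 14.2 FPKM; CDKN1A, the best known target, was at 104 against 122. Of the 22 genes of the unfolded protein response 2 were 2-fold or more higher, with a median of 0.27 and the chaperone HSPA5 at 1181 against 787 FPKM, and the 29 G1/S genes had a median of 0.30. Their percentiles among random lists were 99.91 for G2/M, 98.68 for p53, 99.87 for the unfolded protein response and 99.5 for G1/S. Among lists matched on GC content too they were 93.37, 99.33, 96.59 and 95.68, so that p53 targets alone stayed outside the middle 95%.

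Of the 18 heat shock genes measured in KMS28BM 2 were 2-fold or more higher; the list had a median of 0.13 at percentile 95.92 (94.94 with GC content matched too), or -0.10 with a trimmed-mean scaling, and HSPA6, HSPA1A, HSPA1B and DNAJB1 had ratios of -0.46, -0.09, -0.26 and -0.05. The cytosolic chaperone HSP90AA1 was higher, at 81.5 against 21.6 FPKM, with 17.5% of its words shared with its pseudogene HSP90AA2P. The integrated stress genes had a median of -0.02 with 0 members 2-fold apart, and DDIT4 was at 847 against 940 FPKM. The 31 interferon-stimulated genes had a median of 0.28 at percentile 97.53 (89.67 with GC content matched too), which was -0.13 among genes at 5 FPKM or more and -0.067 with a trimmed-mean scaling. IFI27 was lower, at 69.3 against 241 FPKM, and ISG15 was at 638 against 1039, while IFIT3 was at 39.9 against 21.3. The 19 plasma cell genes had a median of 0.17 at percentile 97.57 (84.27 with GC content matched too), with IRF4 at 53.4 against 35.0 FPKM and ELL2 at 17.4 against 6.66.

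Over the 10472 KMS28BM genes measured, 433 were 2-fold or more higher and 117 lower. With a trimmed-mean scaling, which moved the median of all genes from 0.12 to -0.08, the split was 197 and 170, and the medians were 0.25 for G2/M, 0.13 for p53 targets, 0.049 for the unfolded protein response and 0.09 for G1/S. The largest ratios again belonged to uncertain gene models, DDTL apart, which is protein-coding and shared 16.98% of its words: MIR3652, SNORD26, AL662884, AC010132, PDIA3P1, FAM47E-STBD1, HNRNPA1L2, AL662899, UPK3BL1 and AC023509 were the highest, and INO80B-WBP1, RPL13AP7, SNORD14D, DDTL, ATP6V1G2-DDX39B, AC006064, AC006001, TRMT112P6, RPL17-C18orf32 and RPL36A-HNRNPH2 the lowest. Protein-coding genes with little shared sequence were led by RAB5B, an endosomal GTPase, at 12.5 against 1.35 FPKM, SPATA2 at 9.17 against 1.13, ZSWIM9 at 5.25 against 0.89, ZNF146 at 5.43 against 0.34 and DAZAP2 at 27.9 against 7.22. At the lower end stood DDTL at 0.19 against 10.8 FPKM, MRFAP1 at 15.7 against 58.6, RBM38, an RNA-binding p53 target, at 8.81 against 33.8, and LASP1, an actin-binding protein, at 7.11 against 21.0.

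The GC trend in KMS28BM ran opposite to that in H929. Spearman's rho with GC content across 8922 protein-coding genes was -0.75, and the trend in GC content and length took up 51.0% of the variance. Genes 2-fold higher had a median GC content of 40.7% and a median length of 4116 bases. With the trend removed, 122 genes were higher and 140 lower, and 100 of the 433 higher and 89 of the 117 lower genes kept their place. The medians were then 0.18 for G2/M, 0.12 for p53 targets, 0.06 for the unfolded protein response, 0.07 for G1/S, 0.01 for the interferon genes and -0.030 for the plasma cell genes, at percentiles 99.75, 97.22, 93.6, 94.05, 65.08 and 58.12; heat shock genes had 0.11 at 98.24. Of the G2/M genes 2, of the p53 targets 1 and of the unfolded protein response genes 0 were then 2-fold higher. PMAIP1 was at 1.35, HSP90AA1 at 1.45 and IFI27 at -1.37. Mitochondrially encoded transcripts made up 24.7% of the summed FPKM against 24.0%. As deposited, 8 of these 15 had ratios above 0 in KMS28BM, with a median of 0.01. Only with the trend removed was their median -0.24 in KMS28BM, at percentile 0.86. In H929 it was then -0.24, at percentile 0.12.

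**Figure D3:**
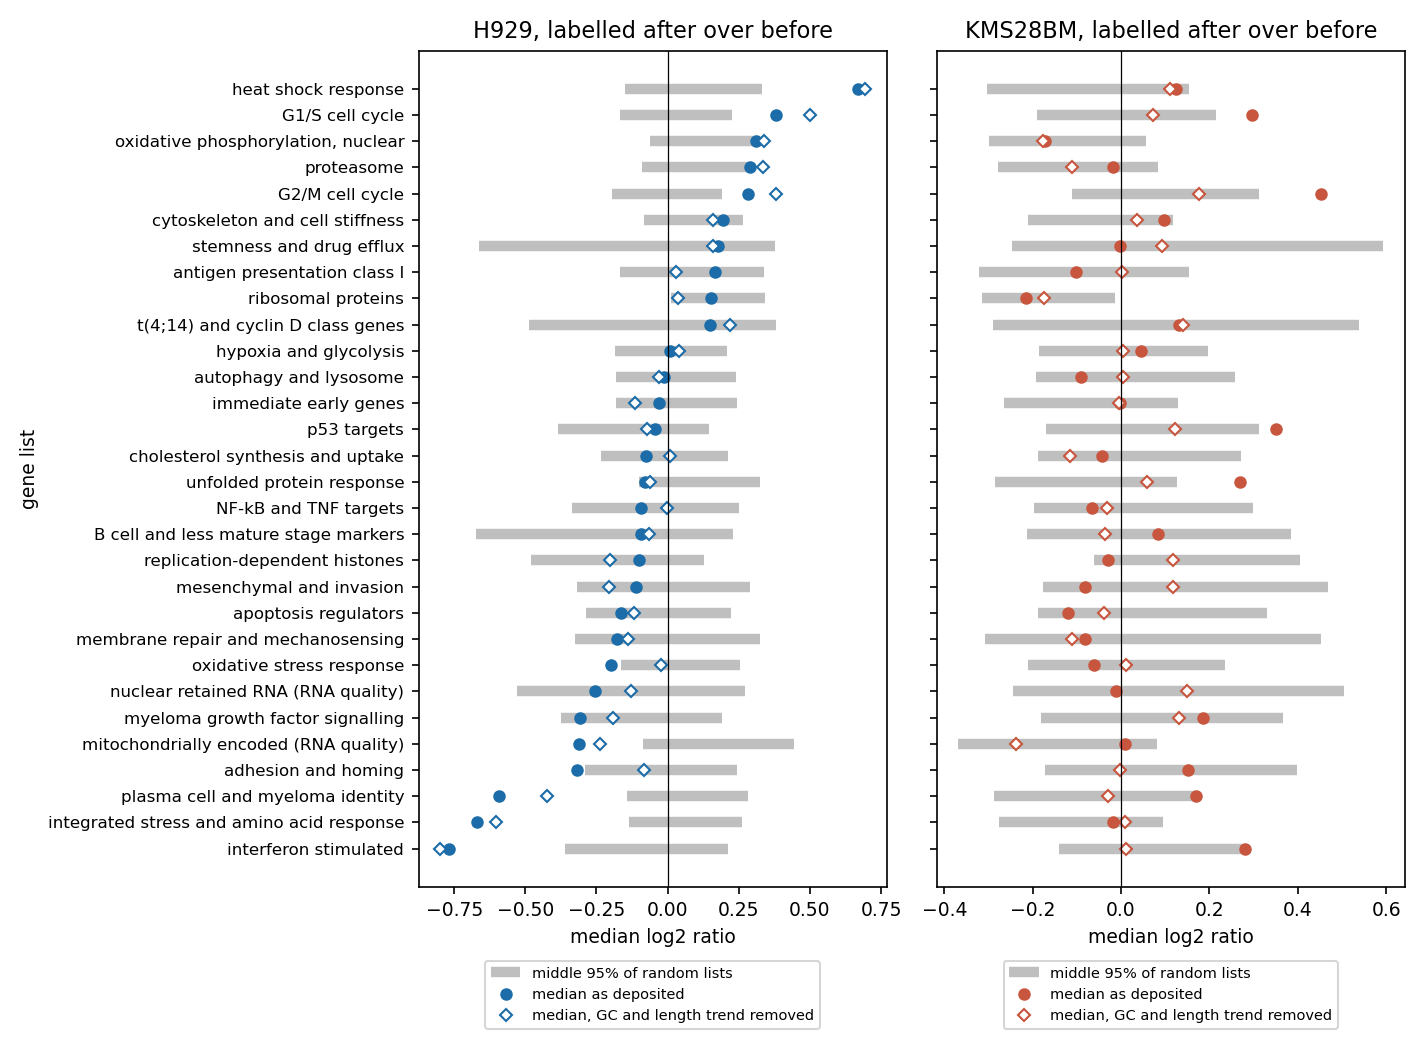
Median log2 ratio, labelled after over before sorting, of the gene lists with 3 or more measured members in both lines; circles are values as deposited, diamonds those with the GC and length trend removed, and grey bars the middle 95% of random lists matched on expression. In H929 heat shock genes lie at 0.67 and interferon genes at -0.77; in KMS28BM G2/M genes lie at 0.45 and move to 0.18 with the trend removed.

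The remaining lists fixed in advance lay within the middle 95% of random lists matched on expression in both lines, apart from epithelial markers in KMS28BM. With GC content matched too, KMS28BM ribosomal proteins lay at percentile 0.74, apoptosis regulators at 1.55, immediate early genes at 98.21 and the cytoskeleton at 99.65, and H929 growth factor signalling at 2.49. With the trend removed, ribosomal proteins in KMS28BM lay at 0.56 and mesenchymal genes in H929 at 2.39. In H929 and KMS28BM the medians were 0.19 and 0.10 for the cytoskeleton, 0.01 and 0.05 for hypoxia and glycolysis, -0.07 and -0.04 for cholesterol synthesis, -0.16 and -0.12 for apoptosis regulators, and -0.03 and -0.0030 for immediate early genes. They were -0.09 and -0.06 for NF-kB targets, 0.17 and -0.10 for antigen presentation, -0.01 and -0.09 for autophagy and lysosome genes, 0.15 and -0.21 for ribosomal proteins, and -0.10 and -0.03 for histones. Medians of -0.11 and -0.08 were found for mesenchymal genes, -0.18 and -0.08 for membrane repair genes, -0.31 and 0.18 for growth factor signalling, and -0.25 and -0.01 for nuclear retained RNA. B cell and less mature stage genes had -0.09 and 0.08, and genes of stemness and drug efflux 0.18 over 4 members and -0.0031 over 7. The t(4;14) and cyclin D class genes had 0.15 and 0.13. Lists that stood apart in 1 line had, in the other, medians of -0.08 for the unfolded protein response and -0.04 for p53 targets in H929, and of 0.15 for adhesion, -0.06 for oxidative stress and 0.01 for mitochondrially encoded transcripts (percentile 92.87, or 0.71 with GC content matched too) in KMS28BM, where oxidative phosphorylation had -0.17 (percentile 0.06 with GC content matched too and 0.88 with the trend removed) and the proteasome -0.02. Single genes of these lists still differed, such as the hypoxia gene BHLHE40 at 23.6 against 7.45 FPKM in H929.

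Few markers of other cells reached 1 FPKM in any library. The highest in each list were CD68 for monocytes, at 10.8 and 11.5 FPKM in H929 and 1.87 and 1.77 in KMS28BM, COL6A3 for stromal cells, at 13.6 and 10.9, ESAM for endothelium, at 7.00 and 9.61 in H929 and 1.73 and 0.67 in KMS28BM, and CFD for fat cells, at 7.52 and 12.98 in H929. GZMB for T and NK cells reached 1.87 FPKM, and LTF for neutrophils 0.30. In KMS28BM HBD stood at 7.16 and 6.57 FPKM and the epithelial factor ELF3 at 32.1 before and 28.3 after; the 5 epithelial markers measured there had a median of -0.29 at percentile 2.2 (17.78 with GC content matched too). None of these lists had more than 6 members at 1 FPKM in any library.

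The design also allows a test of a change shared by the lines, with each line as its own control. Few genes passed, and nearly all of them were uncertain gene models. FAM47E-STBD1 rose in both lines, with a shared log2 change of 3.71 (SE 0.45, adjusted p = 4.184e-13, limma), while STBD1, which lies within the same read-through and shares 57.5% of its words with it, fell by 2.15 (SE 0.40, adjusted p = 8.165e-05, limma). RAB5B rose by 1.83 (SE 0.42, adjusted p = 0.00689, limma), with ratios of 1.14 in H929 and 2.52 in KMS28BM and 0.76% of its words shared. MRPS2 rose by 1.58 (adjusted p = 0.0441, limma) and KCTD20 fell by 1.69 (adjusted p = 0.0123, limma), each with the larger ratio in H929. Of 9261 genes tested, 14 rose and 11 fell on the mean of the lines. Only 19 of these 25 had the same sign in both lines, and 13 were 2-fold apart in the same direction in both. A ratio under 0.5 in size in 1 line was found for 7, and 22 were not protein-coding or shared more than 20% of their words. The prior over genes had infinite degrees of freedom, so a gene's own 1 residual degree of freedom had no weight. The SE therefore does not measure how well the lines agree: it was 0.41 for SNORD58B, with ratios of -6.13 in H929 and 0.06 in KMS28BM. With centring on the median, where the prior had 17.4 degrees of freedom, 2 rose and 3 fell. With the GC and length trend removed 2 rose and 1 fell.

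In the shared fit the heat shock list had the clearest call. Adjusted over the list alone, 4 of its 18 genes rose (HSPA1A, HSPA1B, HSPA6 and DNAJB1), against 1 over all genes tested, HSPA6, and all 4 had ratios below 0 in KMS28BM. No gene of any other list passed when adjusted over the list alone. With a preset correlation of 0.01, limma's camera called heat shock (adjusted p = 5.754e-14), G1/S (adjusted p = 2.544e-05), G2/M (adjusted p = 1.309e-05) and proteasome genes (adjusted p = 0.0272) higher. It called interferon (adjusted p = 1.079e-09), integrated stress (adjusted p = 2.799e-05), mitochondrially encoded (adjusted p = 0.0031) and plasma cell genes (adjusted p = 0.0111) lower. As deposited, the KMS28BM medians of these 4 lists, over all members measured there, were 0.28, -0.02, 0.01 and 0.17. That of the proteasome was -0.02, so these calls rest mainly on H929. Every one of the 8 camera calls was lost with an estimated correlation (adjusted p = 0.893, camera). No list passed by limma's fry, where the smallest adjusted p was 0.4363, of autophagy and lysosome genes, and that of heat shock was 0.8674. Both of these tests rest on 1 residual degree of freedom, where hardly any list could pass. The loss therefore does not decide whether the lists changed.

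Genes that moved the same way in both lines were outnumbered by those that moved apart. Among the 9261 genes measured in both, 16 were 2-fold or more higher in both, against 6.04 expected of independent lists, and 13 were lower in both, against 4.23. ZDHHC18, a palmitoyltransferase, was at 16.6 against 5.03 FPKM in H929 and 18.6 against 6.91 in KMS28BM, PIP4K2C at 9.02 against 3.33 and 12.7 against 4.93, and TSN at 7.56 against 2.80 and 8.58 against 2.91. RPL9P25, SNORD10, AC092368 and RBM14-RBM4 were also higher in both, and SNORD14D, RPSAP14, RPL21P16, AC117378, PPAN-P2RY11 and AMIGO3 lower; they are uncertain for the reason given above. AP000356 was lower too and is missing from the annotation used, so its sharing was not measured. By contrast 102 genes were lower in H929 and higher in KMS28BM, against 17.5 expected, and 9 were higher in H929 and lower in KMS28BM, against 1.46. With the trends removed these counts were 11 and 30, and with a trimmed-mean scaling 37 and 23. Pearson's r between the ratios of the lines was -0.42 and Spearman's rho -0.51 across genes, and with the GC and length trends removed they were -0.18 and -0.25.

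**Figure D4:**
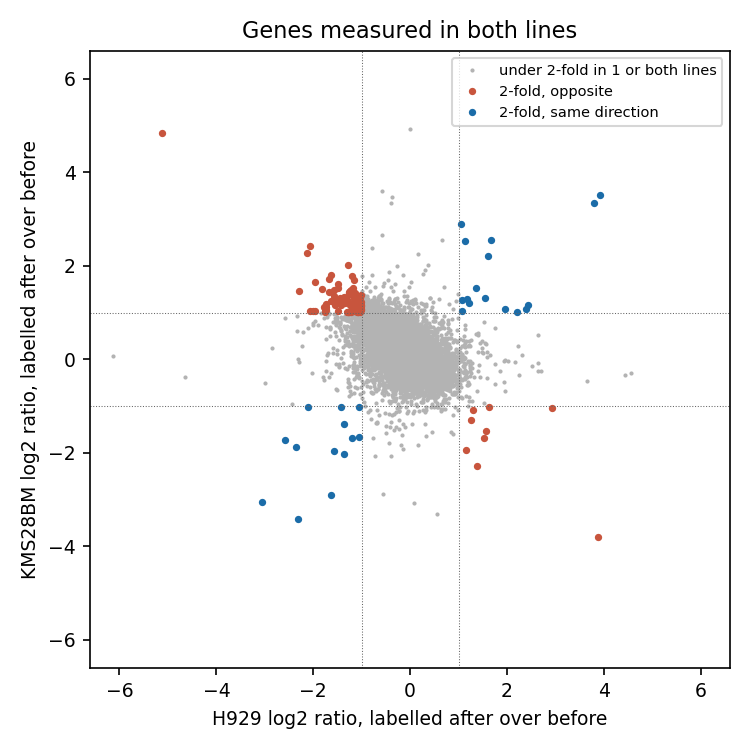
Log2 ratio, labelled after over before sorting, in H929 (x axis) and KMS28BM (y axis) of the 9261 genes measured in both, with 1 point per gene and dotted lines at 2-fold. The 111 genes 2-fold apart in opposite directions (red) lie mostly at the upper left, where 102 were lower in H929 and higher in KMS28BM, and 29 genes share a direction (blue).

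The lines themselves differed far more than the libraries of a line. Between-line levels come from separate tables and are set side by side without a test: 1179 genes were 2-fold or more higher in H929 and 878 in KMS28BM in both states. H929 carried IGHA1, the constant region of IgA, at 6130.3 and 9051 FPKM before and after, with IGKV1-6 at 1212 and 1448, IGHV1-69D at 805 and 978 and the cancer-testis gene PAGE5 at 304 and 369. KMS28BM carried the lambda light chain genes IGLC3 at 6983 and 5527 FPKM, IGLV3-10 at 4609 and 4103 and IGLC2 at 3814 and 3280, and the trypsinogens PRSS2 at 2970.4 and 3046 and PRSS1 at 583 and 545. Of the genes used to class myeloma, FGFR3 was at 162 and 159 FPKM in KMS28BM and 0.47 and 0.43 in H929, and NSD2 lay between 7.16 and 9.63 in all 4 libraries. MAF was at 44.3 and 33.0 FPKM in H929 and 0.055 and 0.076 in KMS28BM. CCND2 was at 30.8 and 15.1 FPKM in H929 and 18.9 and 20.2 in KMS28BM, CCND1 at 1.63 and 1.89 against 0.82 and 0.88, CCND3 between 4.19 and 9.29, and MYC between 3.86 and 5.68. MAFA and MYCN stayed under 1 FPKM in all 4 libraries, and MYCL stood at 4.14 and 4.63 in KMS28BM.

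The authors' deposited table marks 954 genes in H929, 177 up and 777 down, and 586 in KMS28BM, 488 up and 98 down. In both, a mark goes with the authors' p under 0.05, and q-values under 0.05 were listed for 49 H929 and 16 KMS28BM genes. HSPA6 has the smallest p in the authors' deposited table for H929, with a fold change of 24.3. PDIA3P1, a pseudogene, has it in the authors' deposited table for KMS28BM, with a fold change of 21.7. Each of those p-values compares 2 single libraries, so no replicate spread stands behind them.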

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

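The tests of GC content and depth for the opposite ratios, that of handling for the heat shock genes, and the percentiles used for the plasma cell list, were chosen only after the result was seen. The differences between the lines below were not tested, since each line has 1 library per state.

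The ratios of the lines ran in opposite directions: 102 genes were 2-fold lower in H929 and higher in KMS28BM, and 9 the other way, an imbalance that turned to 11 and 30 with the GC and length trends removed and shrank to 37 and 23 with trimmed-mean scaling. A difference in depth is argued against, since the estimated fragments of a line's libraries differed by at most 1.11 times. That small difference did run in opposite directions, from 24.8 to 22.8 M fragments in H929 and from 21.2 to 23.4 M in KMS28BM. Removing the GC and length trends took away 71.4% of the covariance and brought Pearson's r across genes from -0.42 to -0.18, between the bounds set for and against those trends as the whole cause, so this stays open. A swap of the labels in 1 line is a candidate explanation. With the trends removed, 41 genes in all were 2-fold apart in opposite directions and 23 in the same direction. More opposite than same-direction genes is what a swap predicts. However, both counts lay above those expected of independent lists, 4.30 and 4.21, and a swap does not account for the same-direction excess. The counts therefore do not decide on a swap. A remaining technical trend, or lines that respond differently to sorting, would give such counts too, and the latter, a biological explanation, was not tested. The correction itself may also shape the counts, since a trend fitted on protein-coding genes was removed from short RNAs too. SNORD26, of 75 bases, moved from -0.01 to 1.87 in H929. How many of the 41 genes owe their place to this was not measured.

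The heat shock genes were higher in H929, with a median of 0.67 against 0.13 in KMS28BM. GC content and length as the whole cause are argued against, because the list's median stayed at 0.69 with the trends removed. Reads shared between near-identical genes are argued against too as the whole cause, since the 14 members with under 20% of shared words had a median of 0.58. Of these 14, 11 had ratios above 0 and 3 were 2-fold higher, against 6 of all 19 members. Handling common to both lines stays open: the medians lay 0.54 apart, less than the SD of the members in KMS28BM (0.62). That SD is of single genes and is wider than that of random list medians (0.12), so a gap under it decides little. In KMS28BM 2 of 18 members were 2-fold higher and the list stood at percentile 95.92, or 98.24 with the trends removed. However, 0 of the 6 members 2-fold higher in H929 were 2-fold higher in KMS28BM. Handling of the H929 culture alone cannot be separated from sorting with 1 library per state.

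Integrated stress, interferon and plasma cell genes were lower in H929. With the GC and length trends removed the medians were -0.60 for the stress list and -0.80 for the interferon list, which argues against those trends as the whole cause. They are argued against for the plasma cell list too, but only with percentiles chosen after the result was seen. Its median came from -0.59 to -0.42, past the bound set in advance (-0.4) by less than the SD of random lists (0.11). Taken alone, that left the list open. Its median lay at percentile 0 of random lists with the trends removed and of those matched on GC content. A part played by the trends in that list stays open. A difference between sorted and unsorted cells is a candidate explanation that these 4 libraries do not test.

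The H929 median minus the KMS28BM median was -0.76 for the plasma cell list and -1.05 for the interferon list. With the trends removed these differences were -0.39 and -0.81, with trimmed-mean scaling -0.38 and -0.51, and over the 19 and 15 members measured in both lines, a restriction chosen after the data were seen, -0.76 and -0.70. The genes with the largest opposite ratios in the lines were mostly uncertain gene models. The H929 ratio exceeded the KMS28BM ratio by 7.66 for RPL13AP7, 3.11 for SNORA77B, 3.21 for GTF2H4, 3.68 for AC105052 and 2.57 for TMEM230. The difference was -9.98 for AL662884, -4.39 for ZNF146, -4.50 for AC245060, -3.40 for ZSWIM9 and -3.60 for CHURC1-FNTB. TMEM230, ZNF146 and ZSWIM9 shared 5.58%, 0% and 0% of their words with other genes.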

How the results depend on the processing

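Removal of the GC and length trend, the restriction to protein-coding genes and the reversed KMS28BM ratios were chosen after the data were seen. In each setting below, counts are given where they left 1.5 times the count reported, with opposite ones as lower in H929 and higher in KMS28BM, then the reverse. A pseudocount of 0.1 gave 327 genes higher and 1515 lower in H929, 1283 and 214 in KMS28BM, 25 and 28 in both, 527 and 18 opposite, and 1905 higher in H929 and 1327 in KMS28BM between the lines. A pseudocount of 5 gave 60 and 79 in H929, 58 and 36 in KMS28BM, 2 and 3 in both, 7 and 3 opposite, and 4 and 4 by limma. Without a filter Spearman's rho was -0.27 and limma called 38 and 53 of all genes listed, where its spread is unreliable because most residuals are 0. At 5 FPKM, with fewer genes, 309 were lower in H929, 268 higher and 66 lower in KMS28BM, 10 and 5 in both, 61 opposite (lower in H929), 5 and 5 by limma, and 567 higher in KMS28BM between the lines. Centring gave 2 and 3 by limma. Trimmed-mean scaling gave 378 and 328 in H929, 197 higher in KMS28BM, 37 and 23 opposite, and 7 lower by limma. Rescaling to genes with symbols gave 116 higher in H929, 10 and 7 in both, and 1 and 0 by limma. It left 86 genes at an unadjusted limma p under 0.05, against 142 in the main setting. That count was 84 at 5 FPKM, 215 with the GC and length trend removed and 768 without a filter. At 1.5-fold the counts were 820 and 2079, 1928 and 451, 47 and 48 in both, and 827 and 80 opposite; at 4-fold they were 23 and 36, 26 and 19, 2 and 2, and 3 and 1. Without a trend in the moderation limma called 7 lower. Protein-coding genes alone gave 71 lower in KMS28BM, 9 and 7 in both, and 7 and 5 by limma. With the GC and length trend removed, 259 were lower in H929, 122 higher in KMS28BM, 11 and 30 opposite, rho was -0.25, and limma called 2 and 1. Reversing KMS28BM gave 9 and 102 in both. Except for the filter and the number of genes tested, the cause was not tested.

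List medians that lay outside the middle 95% of random lists matched on expression turned sign in 5 cases: G2/M in H929 without a filter (-0.051), oxidative stress in H929 with trimmed-mean scaling (0.046), plasma cell genes in KMS28BM with the trends removed (-0.030), and interferon genes in KMS28BM at 5 FPKM (-0.13) and with trimmed-mean scaling (-0.067). Of all 61 medians, near 0 or not, 20 turned sign with trimmed-mean scaling, 13 with the trend removal, 10 of 58 at 5 FPKM, 10 of 59 with rescaling, 5 without a filter, 1 with centring and 1 with a pseudocount of 0.1. Apart from those 5 cases, trimmed-mean scaling moved 52 list medians by more than the spread of random lists, the trend removal 15, 5 FPKM 14, no filter 8, a pseudocount of 5 moved 7, rescaling 5 and a pseudocount of 0.1 moved 1. Of 236 ratios of named genes, 69 moved with a pseudocount of 0.1 and 41 with the trend removal, and none that was 2-fold turned sign under these or centring. No paired analysis was possible because each group holds 1 library, other than the shared test, which pairs the libraries of a line; leaving out either line leaves no residual degrees of freedom and so no test. Depth limits low genes: 1 FPKM on 2000 bases stands for between 42.4 and 49.5 fragments.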

Other observations

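The pathway scan and its ranking were chosen after the data were seen; pathways came from the annotation deposited with the values. With the GC and length trend removed, the 225 spliceosome genes measured in H929 had a median log2 ratio of 0.26, above the middle 95% of random lists (-0.02 to 0.10), the 119 genes of ribosome biogenesis had 0.24, the 42 genes of DNA replication 0.38 and the 33 genes of the citrate cycle 0.36. The 55 genes of neuroactive ligand and receptor interaction had -0.35. In KMS28BM the 255 ribosome genes had a median of -0.17 against -0.08 to -0.01 for random lists, and the 121 genes of oxidative phosphorylation -0.13, where the 120 measured in H929 had 0.20. These values describe single libraries, and 278 pathways were scanned in H929 and 283 in KMS28BM.

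Across lines the H929 library labelled after sorting was closest to the KMS28BM library labelled before sorting, with Pearson's r across 9261 genes of 0.88. The 2 libraries labelled after sorting had 0.853 and the 2 labelled before 0.844. The other crossed pair, H929 labelled before and KMS28BM labelled after, had 0.845. These values keep the GC trends, which ran opposite in the lines. They restate the opposite ratios given above and are no separate evidence on the labels. Within a line r was 0.95 for H929 and 0.96 for KMS28BM. EPRS1, a glutamyl-prolyl tRNA synthetase, was at 9.72 against 32.3 FPKM in H929 and 59.8 against 16.5 in KMS28BM, with ratios of -1.63 and 1.80. Of the 954 genes marked in the authors' deposited table for H929, 417 were 2-fold apart on the scale used here, and of the 586 for KMS28BM, 237; 229 and 169 were under 1 FPKM in both libraries.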
